A study of Arabidopsis thaliana with 2 samples.

How the data were processed

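Gene expression was measured in siliques, the seed-bearing fruits of Arabidopsis thaliana, of the rge1-1 mutant and of the Col-0 wild type at 12 DAF. Per the labels' protocols, plants were grown at 22 °C with 16 h of light and 8 h of dark, total RNA was isolated with an RNAqueous kit, and labelled RNA was made by linear amplification with an Agilent low-input kit. Each of the 2 samples is a 2-colour array. Per the labels, both arrays carried rge1-1 RNA in the Cy3 channel and Col-0 RNA in the Cy5 channel, and 0 arrays had swapped dyes. A bias of a probe towards one dye therefore has the same sign on both arrays and cannot be separated from the genotype. The labels number the arrays as replicates 1 and 2 and do not say that these came from separate plants, so p-values measure only the spread between these 2 arrays, which may be technical.

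The authors deposited 1 table with a log ratio of the 2 channels for each of 21500 probes on each array. Per the submitters' processing notes the software was Agilent Feature Extraction 7.1.1. Background correction, dye normalization within the array and probe filters are not given in the sources used here, and scanner intensities were not used here. The deposited values were read as log10 ratios because they are signed, have 3 significant digits and hold 386 and 474 exact zeros on the arrays, which is the form of this software's log ratio. The base of the logarithm is not written in the table, so every fold given here assumes base 10. The order of the ratio is also unknown. The software writes Cy5 over Cy3, which would be Col-0 over rge1-1, whereas the sample titles name rge1-1 first. Signs are given as deposited, and neither sign is assigned to a genotype. The direction check fixed before the data were examined rested on RGE1 and its dependent gene ALE1, and 0 of the named probes carry either name. The table was not centred: the array medians were 0.0481 and 0.00672 on the log10 scale, or 0.16 and 0.02 on the log2 scale, for replicates 1 and 2.

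Probes were named from the platform annotation of 2007, updated through gene IDs to the symbols of the TAIR10.1 gene table. Of the 21500 probes, 8893 had 1 gene name, 39 had several and were not named, and 12568 were unnamed here. Of the probes with 1 name, 8875 matched the gene table by gene ID and the others kept the name of the annotation. Because no build is tied to the probes, the gene table was used only for names and for which genes neighbour each other, and no coordinates are given. Log10 ratios were multiplied to the log2 scale, probes of 1 gene were averaged (71 genes had over 1 probe), and 21426 rows, of which 8819 were named genes, entered the tests. The probes of a gene differed by a median of 0.29 on the log2 scale and by over 1 in 4 genes.

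The log ratio of each row was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept only, then eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). Each row has 1 residual degree of freedom, to which eBayes added 1.97 from the prior. Because so few degrees of freedom were left, a count without a p-value was fixed as well: rows at least 2-fold from equal in 1 direction on both arrays, set beside rows at least 2-fold from equal with opposite signs. The number of arrays limits the precision, and no read depth applies. Gene lists of 15 pathways or cell types, with 249 members, were fixed before the data were examined. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 13 lists with at least 2 named members. The rule for named genes took RGE1, ALE1, the 10 named genes of each sign with the largest mean among those past the test, filled up by the largest value of the smaller of the 2 absolute ratios, and up to 4 members of each list.

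The tests were run on simulated data with 200 changed rows among 21426, drawn with the spread that limma fitted to the real arrays. Over 20 such draws limma called between 0 and 72 of the 200 changed rows, with a median of 0, and 9.81% of all its calls were unchanged rows. With the spread fitted after values of exactly 0 were left out (20761 rows), it called between 153 and 177 of the 200 changed rows, and 9.75% of all its calls were unchanged rows. Both shares pool the calls of all draws, whereas the threshold of 0.05 limits the average share per draw. With all rows the pooled share rests on the draws that made calls, so it does not show that the threshold was exceeded. Without values of exactly 0 every draw made calls, and in those draws limma's calls held more unchanged rows than the threshold names. The draws gave a row the same spread on both arrays, centred on 0. The real arrays had median absolute deviations of 0.28 and 0.18 on the log2 scale, and medians of 0.16 and 0.02. The recovery and the shares therefore describe the draws and need not hold for the real calls. The count without a p-value found 13, 46, 50 and 50 of 50 rows changed by 2-, 4-, 8- and 16-fold in 1 simulation with all rows. It also counted 150 unchanged rows there, and limma called 0 of 50 at each fold. That simulation's noise gave 165 unchanged rows of opposite signs against 16 rows in the data. Its recovery is therefore no guide to the real count. The fitted prior degrees of freedom ran from 1.92 to 2.23 over the draws with all rows, where the true value was 1.97, and from 4.76 to 7.36 over the draws without values of exactly 0, where it was 4.90. Camera called 3 of 3 simulated lists shifted by 1.5 on the log2 scale and 0 of 10 lists that were not shifted. The medians of the real lists reached at most 0.62, and shifts of that size or smaller were not simulated.

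Alternatives changed the centring and scale of the arrays, the moderation of the variance, the averaging of probes, the treatment of values of exactly 0, the thresholds, the log base and the test of the lists, and left out each array in turn. Values left without a gene name were kept in the counts and are not described singly.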

Results

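The series compared siliques of rge1-1, a mutant with retarded growth of the embryo, with siliques of the Col-0 wild type at 12 DAF. RGE1, also named ZHOUPI, encodes a basic helix-loop-helix transcription factor of the endosperm, the tissue that surrounds and feeds the embryo. The comparison asks which transcripts differ in abundance between mutant and wild-type fruits, which hold seeds, seed coats and fruit wall together. Expression was measured on 2 replicate 2-colour arrays of 21500 probes, each hybridised with rge1-1 RNA in Cy3 and Col-0 RNA in Cy5. The log ratios had an SD of 0.53 on the log2 scale across probes on replicate 1 and 0.34 on replicate 2. Exact zeros made up 386 values on replicate 1 and 474 on replicate 2. The table does not state which genotype is the numerator, so a positive or negative ratio is the deposited sign and not a rise or fall in the mutant. If the values are Cy5 over Cy3, positive is Col-0 over rge1-1; read by the sample titles it is the reverse. Log2 values and folds assume that the deposited logarithm has base 10, which is likely and not stated.

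RGE1 itself could not be checked, because 0 of the named probes carry its name, and the same holds for ALE1, a subtilisin-like protease gene of the embryo surface whose expression depends on RGE1. The order of the ratio therefore remained open for every gene.

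Among named genes, the ratios furthest from equal were negative on both arrays. With 0 arrays of swapped dyes, a bias of a probe towards one dye cannot be separated from the genotype in these ratios. AT5G53500, which encodes a WD40-repeat protein, had the largest mean of any named gene, with a log2 ratio of -5.80 ± 0.59 (SD, n = 2), or 55.6-fold. AT2G32910, a gene for a protein with a DCD (development and cell death) domain, and AT1G71940, a gene of the SNARE-associated Golgi protein family, each had a mean of -4.85, with SDs of 0.14 and 0.38 (n = 2), or 28.8-fold. HIS1-3, a linker histone gene induced by drought and abscisic acid, had a mean of -4.67, with -5.45 on replicate 1 and -3.89 on replicate 2, and AT1G18000, a gene of the major facilitator superfamily of transporters, stood at -4.34 ± 0.12 (SD, n = 2).

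The other negative genes under the naming rule had smaller ratios. AT1G61100 had a mean log2 ratio of -3.70 ± 0.21, AT4G10930 one of -3.34 ± 0.20 and AT3G09690 one of -3.13 ± 0.27 (SD, n = 2 each). AT2G44770, an ELMO/CED-12 family gene, had a mean of -2.68 ± 0.23, and AT4G15940, a fumarylacetoacetate hydrolase family gene, one of -2.44 ± 0.11 (SD, n = 2 each).

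Positive ratios were smaller. The largest of the 10 named genes was AT2G47440, which encodes a tetratricopeptide-repeat protein, with a mean log2 ratio of 1.75 ± 0.01 (SD, n = 2), or 3.36-fold. AT5G59140, a BTB/POZ domain gene, had a mean of 1.48 ± 0.0023, and AT5G61310, a gene for a cytochrome c oxidase subunit, one of 1.47 ± 0.15 (SD, n = 2 each). UGT72E1, a glucosyltransferase gene of phenylpropanoid metabolism, stood at 1.43 ± 0.23, and FZL, a gene for a dynamin-like protein of chloroplast thylakoids, at 1.49 ± 0.51 (SD, n = 2 each). AT3G47650, a DnaJ-type zinc-finger gene, had a mean of 1.36 ± 0.18, and AT1G72820, a mitochondrial carrier family gene, one of 1.37 ± 0.26 (SD, n = 2 each). AT5G14970 had a mean of 1.49 ± 0.36 (SD, n = 2). The arrays were further apart for AT1G13350, with a mean of 1.74 ± 0.86, and for AT5G19900, with one of 1.64 ± 0.79 (SD, n = 2 each).

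**Figure D1:**
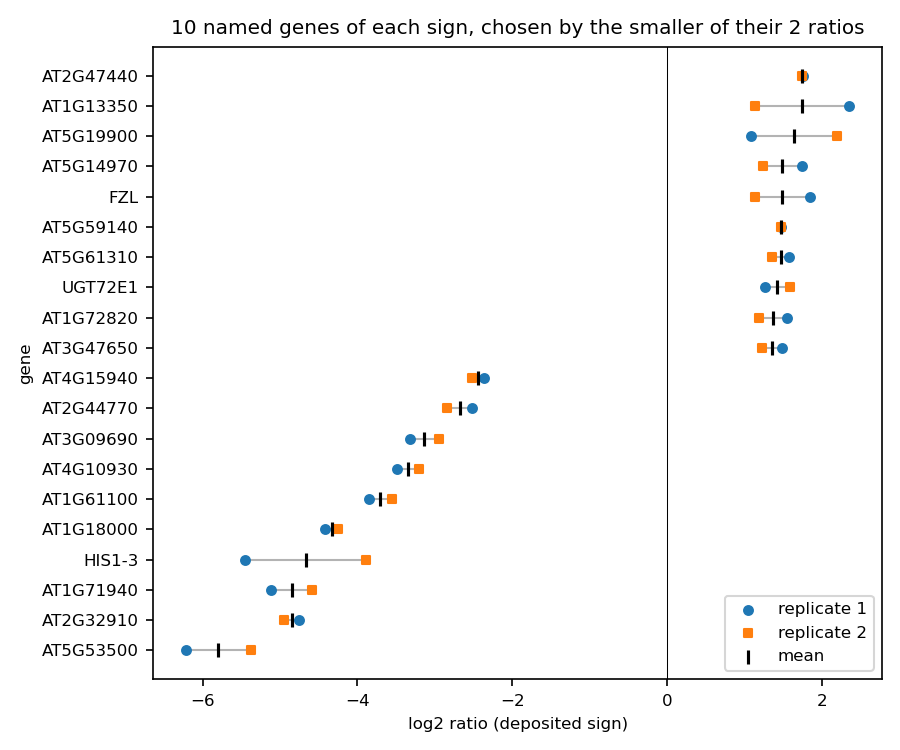
Log2 ratio (horizontal axis, deposited sign) of the 10 named genes of each sign (vertical axis) on replicate 1 (circles) and replicate 2 (squares), with the mean as a vertical tick and a line joining the arrays. The means of the negative genes reach -5.80 (AT5G53500), and those of the positive genes reach 1.75 (AT2G47440).

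None of these genes passed the main test. With limma and Benjamini-Hochberg adjustment, 0 of 21426 rows had an adjusted p under 0.05, and the smallest adjusted p was 0.336. At an unadjusted p under 0.05 limma counted 1415 rows, of which 754 were positive and 661 negative, where chance alone gives 1071. Robust limma counted 1537 rows there and the statistic with no moderation 1063, and both also had 0 rows at an adjusted p under 0.05. With the arrays as deposited, the call depended on how values of exactly 0 were treated. When rows with such a value on either array were left out, as an alternative fixed beforehand, limma called 55 of 20761 rows, 46 negative and 9 positive, and these included all 10 named negative genes and 3 of the positive ones, AT2G47440, AT5G59140 and AT5G61310. That count returned to 0 when the arrays were also centred on their medians, with a smallest adjusted p of 0.301.

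Counted without a test, 148 rows were at least 2-fold from equal with 1 sign on both arrays, 108 negative and 40 positive, while 16 rows were as far from equal with opposite signs. Arrays whose rows were paired without relation would give 15.6 rows of 1 sign. Among the 21226 unchanged rows of 1 simulation, where noisy rows are noisy on both arrays, 150 were that far apart with 1 sign and 165 with opposite signs. Noise drawn evenly around 0 gives both kinds of sign alike by construction, so the imbalance of 148 against 16 sets the data apart from it. The level of the simulated noise is no guide to the 148, since its 165 rows of opposite signs are far above the 16 in the data. If the deposited logarithm has base 2, the count of 1 sign is 14, all negative. At 3-fold the counts were 40 negative, 6 positive and 0 with opposite signs. Of the 148 rows, 46 negative and 16 positive ones were named genes. Across the 21426 rows, which are not independent replicates, the log ratios of the 2 arrays had a Pearson correlation of 0.335 and a Spearman correlation of 0.273.

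**Figure D2:**
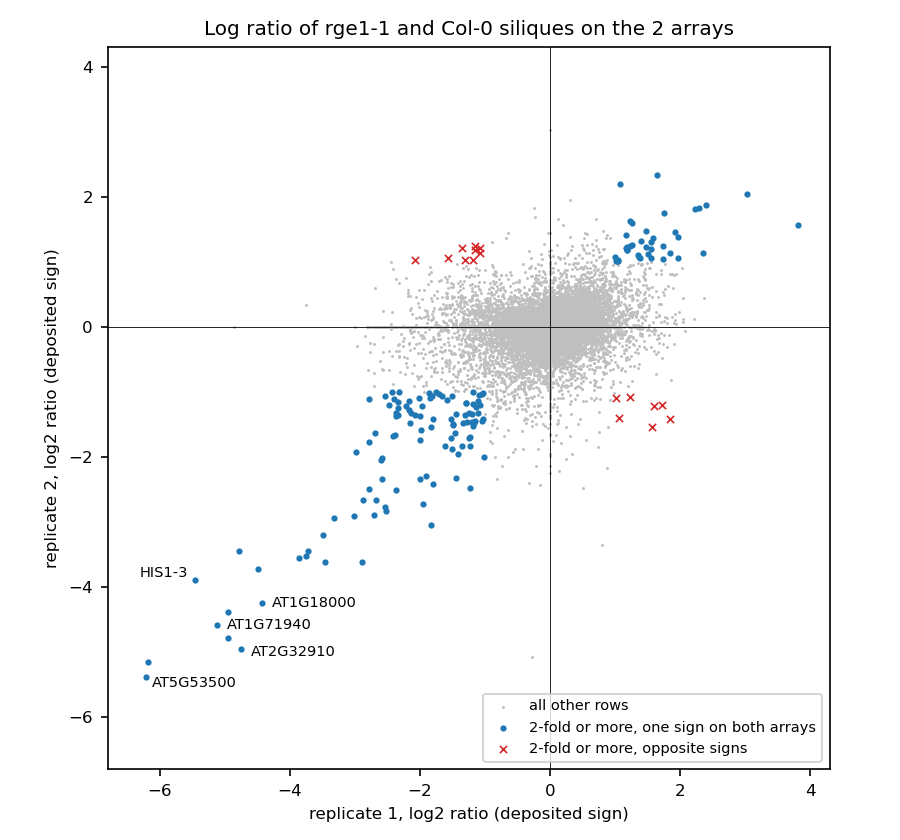
Log2 ratio on replicate 1 (horizontal axis) against replicate 2 (vertical axis), deposited sign, one point per gene or unnamed probe. Blue points mark the 148 rows at least 2-fold from equal with 1 sign on both arrays, which extend furthest at the lower left, and red crosses mark the 16 rows with opposite signs.

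Of the 249 genes in the 15 fixed lists of pathways and tissues, 65 had a named probe, 0 of these were at least 2-fold from equal with 1 sign on both arrays, and 0 passed limma's test over all rows. Over all named genes 62 of 8819 were that far from equal, so 0 of 65 is near the general share. It does not show that these genes were unchanged. By camera, 0 of the 13 tested lists had an adjusted p under 0.05, and 1 had an unadjusted p under 0.05. The results for the lists hold only for the named members, which for several lists were few.

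The list with the unadjusted p under 0.05 was the one fixed under the heading of the RGE1 pathway of the embryo surface, of which 2 of 8 members were named. Whether each member acts in the pathway of RGE1 was not tested here. ACR4 (CR4 in the gene table), a receptor kinase gene of the embryo epidermis, had a mean log2 ratio of 0.80 ± 0.26, and GSO1, a receptor kinase gene needed for the embryo cuticle, one of 0.43 ± 0.06 (SD, n = 2 each). Both were positive on both arrays, and 2 of 2 passed limma's test adjusted over the list alone, against 0 over all rows. Adjusting over 2 genes corrects for few tests and not for the choice among 13 lists. By limma 1415 of 21426 rows had an unadjusted p under 0.05, so these 2 passes add no support for the list. The list median was 0.62, or 0.53 with centring. Camera gave the list p = 0.0137, adjusted p = 0.178, and over the alternatives an adjusted p from 0.0551 with centring to 0.896 with an estimated correlation.

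No list of seed filling genes passed the test. Of the storage protein genes 4 of 12 were named, with a median log2 ratio of 0.16, or 0.06 with each array centred on its median, and camera adjusted p = 0.746. The median was 0.26 on replicate 1 and 0.07 on replicate 2. The globulin gene PAP85 stood at 0.19 ± 0.12 and AT2G28490, a vicilin-like gene, at 0.18 ± 0.03 (SD, n = 2 each), while AT1G03890, a cupin gene, was 0.33 on replicate 1 and -1.15 on replicate 2. AT4G36700 stood at 0.13 ± 0.15 (SD, n = 2). The 4 named oil body genes of 10 had a median of -0.07, or -0.16 with centring (adjusted p = 0.746), with AT3G18570 at 0.44 ± 0.46, AT2G25890 at -0.35 ± 0.23, OLEO3 at -0.13 ± 0.17 and AT3G01570 at -0.0084 ± 0.04 (SD, n = 2 each).

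Late embryogenesis abundant genes, whose proteins accumulate as seeds prepare to dry, had 13 of 19 members named. Of these 6 were positive and 3 negative on both arrays. Their median was 0.04, or -0.05 with centring, their mean -0.02 and camera's direction down (adjusted p = 0.746). The furthest were AT4G21020 at -0.68 ± 0.41, AT5G44310 at -0.44 ± 0.33, M17 at 0.28 ± 0.12 and M10 at 0.27 ± 0.43 (SD, n = 2 each). The seed maturation regulators EEL and BZIP53, 2 of 11 listed, stood at 0.10 ± 0.08 and 0.08 ± 0.03, with a list median of 0.09 that centring brought to -0.0057. The acyl-ACP thioesterase genes FaTA and FATB, 2 of 20 genes of oil synthesis, stood at 0.30 ± 0.31 and 0.02 ± 0.08 (SD, n = 2 each). The median of the thioesterase genes was 0.16, or 0.07 with centring. Both lists had a camera adjusted p of 0.746.

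Of the endosperm markers 5 of 13 were named, with a median of -0.09, or -0.18 with centring, and camera adjusted p = 0.699. AGL62, a MADS-box gene that keeps the young endosperm from forming cell walls, had a mean log2 ratio of -0.66 ± 0.36 (SD, n = 2), negative on both arrays. PHE2 (AGL38 in the gene table) was -0.79 on replicate 1 and 0.0011 on replicate 2. AT1G71250, a GDSL lipase gene, was 0.62 and -0.04, and AGL28 stood at -0.09 ± 0.0059 (SD, n = 2).

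Expansins had ratios of both signs, and 0 of the 13 named ones passed limma's test, also when adjusted over the list alone. Among 13 named expansins of 25, which loosen cell walls, 6 were positive and 5 negative on both arrays, and the median was 0.11, or 0.02 with centring, while camera's direction was down (adjusted p = 0.746). On single arrays the median was 0.08 on replicate 1 and 0.0066 on replicate 2. EXPA15 had a mean of -0.57 ± 0.51, EXPA7 one of 0.40 ± 0.28, EXPA18 one of -0.28 ± 0.25 and EXPA20 one of 0.26 ± 0.25 (SD, n = 2 each). The 6 named xyloglucan endotransglucosylase/hydrolase genes of 20 had a median of 0.01, which turned to -0.08 with centring and -0.02 with scaling, a mean of -0.06 and camera's direction down (adjusted p = 0.746). XTH20 stood at -0.47 ± 0.55, XTH33 at 0.36 ± 0.19 and XTH16 at 0.13 ± 0.23 (SD, n = 2 each), and XTH32 was -0.76 on replicate 1 and exactly 0 on replicate 2. The pectin genes VGD1 and ADPG1, 2 of 13 listed, stood at 0.26 ± 0.10 and 0.02 ± 0.02 (SD, n = 2 each; adjusted p = 0.746), and their median of 0.14 was 0.05 with centring.

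Markers of the other tissues of the silique showed no common shift that passed the test. Of the seed coat and flavonoid genes 4 of 20 were named, with a median of 0.07, or -0.02 with centring (camera adjusted p = 0.746). AT3G50990, the seed coat peroxidase gene PRX36, stood at 0.42 ± 0.0070, ARA12 at -0.10 ± 0.19, DFR at 0.09 ± 0.25 and BAN at 0.05 ± 0.34 (SD, n = 2 each). The 4 named photosynthesis genes of 27 had a median of -0.0064, or -0.10 with centring (adjusted p = 0.746). RCA, the gene of Rubisco activase, was -1.22 on replicate 1 and 0.24 on replicate 2, and LHCB4.1, a light-harvesting protein gene, had opposite signs on the arrays with a mean of 0.14 ± 1.49 (SD, n = 2). PSAN stood at -0.13 ± 0.0035 and PSAE-1 at 0.12 ± 0.42 (SD, n = 2 each). Among 3 named cell cycle genes of 20 the median was 0.02, or -0.07 with centring (adjusted p = 0.778). PRL, a subunit gene of the MCM helicase, stood at 0.43 ± 0.29 (SD, n = 2), AUR1 at 0.02 ± 0.27 (SD, n = 2), and the mitotic kinase gene AUR2 was 0.71 on replicate 1 and -1.09 on replicate 2. PDF1.2, the 1 named defence gene of 11, stood at 0.11 ± 0.17 (SD, n = 2). The cuticle and epidermis list had 0 of 20 members named and was not tested. Centring shifts replicate 1 by its median of 0.16 and replicate 2 by 0.02, so it moves the means of the 2 arrays by the average of these. Each list median that changed sign was smaller than that average, narrowly so for the seed maturation regulators, which went from 0.09 to -0.0057. Other list medians also differed between the arrays, with 0.11 on replicate 1 and -0.03 on replicate 2 for late embryogenesis abundant genes, 0.13 and -0.02 for the xyloglucan enzymes. They were 0.29 and 0.02 for oil synthesis, -0.02 and -0.08 for oil bodies and -0.08 and -0.04 for the endosperm. They were 0.18 and 0.10 for pectin, 0.16 and 0.04 for the seed coat, 0.14 and -0.15 for photosynthesis, and 0.63 and -0.18 for the cell cycle.

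**Figure D3:**
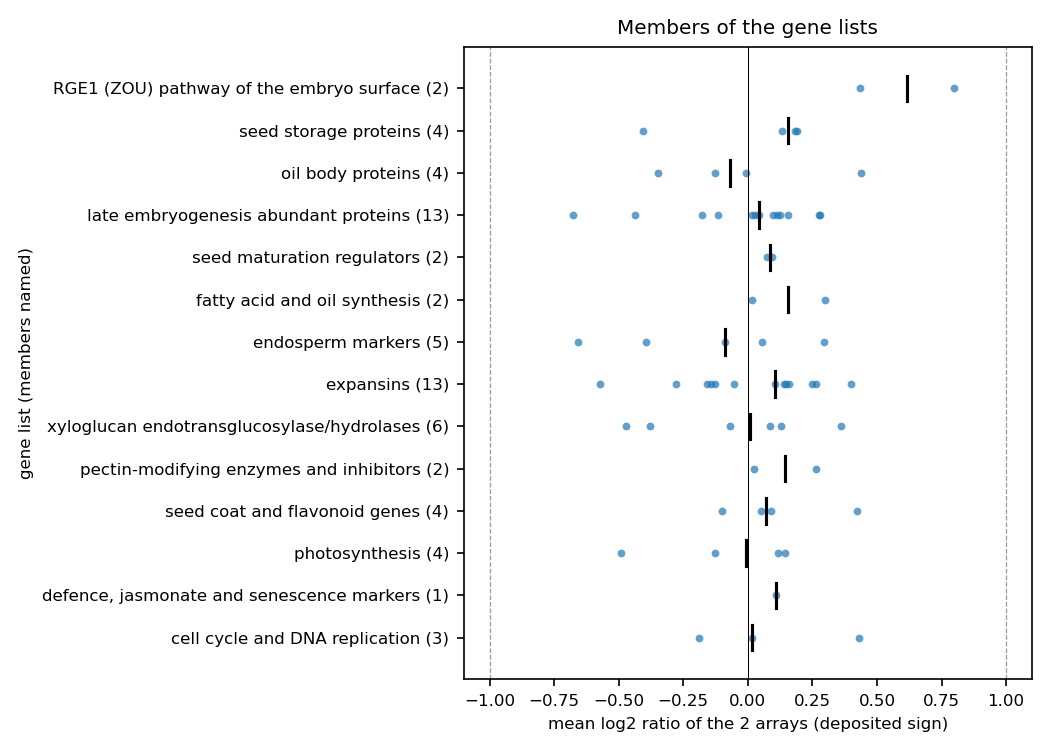
Mean log2 ratio of the 2 arrays (horizontal axis, deposited sign) of each named member of the gene lists (vertical axis, number of named members in parentheses), with the list median as a black bar and dashed lines at 2-fold. The 65 members lie between the dashed lines, and the embryo surface list has the highest median, 0.62.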

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

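The alternatives that subtract a running median along probe IDs, read the values as log2 in the 2-fold count, leave out only rows at 0 on both arrays, combine the zero filter with centring or scaling, or drop zeros from the 2-fold count and the correlation were chosen after seeing the data. The count of 0 limma calls held with centring, scaling to one median absolute deviation, robust eBayes, no moderation, each probe alone, an adjusted p under 0.10 in the main test and the running median (smallest adjusted p between 0.0748 and 0.808 over the refitted ones). The smallest, 0.0748, came from robust eBayes, which would therefore make calls at 0.10. An added 2-fold limit and log2 values could not move it by construction. Without values of exactly 0 it was 55, 46 negative and 9 positive. Without rows at 0 on both arrays it was 30, all negative, so no positive gene was called there. The filter of values of exactly 0 gave 0 again with centring or scaling. The prior degrees of freedom moved from 1.97 to 4.90 without the zeros and to 1.91 with centring as well, and the prior SD moved with it. With all rows kept and centred they were 1.87, also with 0 calls. Once the arrays were centred, leaving out the zeros thus made little difference to the prior and none to the count. The cause was not tested further. At unadjusted p under 0.05 robust limma counted 1537 rows and the unmoderated statistic 1063. The same-sign 2-fold count of 148 became 544 at 1.5-fold, where 148 rows had opposite signs, and 46 at 3-fold. With 1 array left no agreement of sign is required, and rows at least 2-fold from equal on that array were counted instead. These were 419 without replicate 1 and 1352 without replicate 2, and such counts cannot fall below 148 by construction. The same-sign count was 14, all negative, if the values are log2. It was between 149 and 164 with centring, each probe alone or the running median, and its negative share ran from 72.5% to 80.5% there. Leaving out zeros could not change it, since a row at 0 is never 2-fold from equal on both arrays. The correlation of 0.335 turned to -0.0390 when the 10% of rows with the largest absolute mean were left out. That cut lowers any correlation by construction, since 100 random pairings of the arrays gave a median of -0.153 and a highest value of -0.130 under it, and the observed value lies above these. Without zeros the correlation was 0.363. For the lists 0 passed under centring, scaling, an estimated correlation, ranks or fry. With centring, scaling, robust eBayes, no moderation or each probe alone 0 of the 20 named genes passed the test, whereas 13 passed without the zeros. Their signs could hardly turn, since they were chosen for large ratios of 1 sign on both arrays. For the lists 3 medians on 1 array moved by more than the members' SD, seed maturation regulators without either replicate and cell cycle without replicate 2. No call can be made with 1 array left, and RGE1 had no value to vary. The main test was itself paired, since each array holds both genotypes and the log ratio is taken within the array. With only 1 group of arrays no further pairing was possible.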

Other observations

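The comparison with random pairings of the arrays, the running median, the test of probes at exactly 0 and the scan of gene families were chosen after the result was seen.

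Outside the naming rule, and chosen here after their values were seen, several of the 62 named genes at least 2-fold from equal with 1 sign on both arrays have known functions, and 0 of the 62 passed limma's main test. Without values of exactly 0 limma called 21 of them, among those named here ATERDJ2A and AT3G62870 but not UBP21, PMM, Haspin or AGL26, and with centring as well it called 0. On the negative side ATERDJ2A, a J-domain gene of protein import into the endoplasmic reticulum, had a mean log2 ratio of -2.02 ± 0.51, AT3G62870, a ribosomal protein gene of the L7Ae family, one of -1.87 ± 0.19, and UBP21, a ubiquitin-specific protease gene, one of -1.80 ± 0.77 (SD, n = 2 each). PMM, the phosphomannomutase gene of GDP-mannose and ascorbate synthesis, stood at -2.16 ± 0.75, and Haspin, a histone kinase gene of mitosis, at -1.12 ± 0.02 (SD, n = 2 each). AGL26 reached -1.35 as a mean of 2 probes that disagreed, at -3.10 and 0.40. In a scan of 16 families defined by the start of the gene symbol, 0 passed camera. The serine carboxypeptidase-like genes (SCPL) came first, with 14 of 21 members positive and 2 negative on both arrays and a median of 0.19, or 0.10 with each array centred on its median, against a median of 0.08 over all rows before centring (adjusted p = 0.595 and, with an estimated correlation, adjusted p = 0.996).

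The first pattern is the agreement of the arrays in the tail: 148 rows at least 2-fold from equal with 1 sign against 16 with opposite signs. Independent noise on the arrays is argued against, since the highest of 100 random pairings gave 27 such rows. Random pairing does not keep a spread that a row has on both arrays. Noise of that kind, drawn evenly around 0, gives both kinds of sign alike by construction, as in the simulation (150 and 165 unchanged rows). The 148 against 16 argue against that form of noise only, and noise that leans to 1 sign was not simulated. A position effect shared by the arrays stays open: after a running median along probe IDs was subtracted 164 rows were of 1 sign and 13 of opposite signs, but neighbouring IDs correlated by only 0.0531 and 0.0234, so IDs may not follow position. A bias of single probes towards one dye stays open, because 0 arrays had swapped dyes and such a bias could give the same sign on both arrays. The genotype, which the design names, is open beside these and untested.

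The second pattern is the longer negative tail of replicate 1, where 936 rows lay at or below a log2 ratio of -1 against 306 on replicate 2, a ratio of 3.06. Probes at exactly 0 were a candidate cause, since the 279 probes at 0 on replicate 2 alone had a median of -0.91 on replicate 1, but without any such probe the ratio was still 2.95. An offset of replicate 1 towards negative ratios is argued against by its median, which is positive at 0.16 against 0.02 on replicate 2, while centring gave 3.78 and decides nothing further because those medians fix its direction. Bringing both arrays to one median absolute deviation lowered it to 1.31, between the limits set for and against a wider spread of the whole array, so that explanation remains undecided. No biological explanation was tested, since both arrays compare the same genotypes.

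The third pattern is where the genes lie. A mutant line could carry a chromosome segment of another origin around the mutated gene, and a hypothesis was that the genes with large ratios cluster there. Of the 62 named genes 1, AT1G51570 at a mean of -1.73, lay within 500 genes of RGE1 on either side, or 1.61%, with an exact 95% upper limit of 8.66%. This argues against such a segment as the source of most of them, and 2.60% of all named genes lie in that window. Runs of neighbours stay undecided, with 1 pair within 5 genes (AT5G61290 and AT5G61310) against a median of 0 in 10000 random draws (one-sided permutation p = 0.451).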
